A study of Mus musculus with 43 samples.

How the data were processed

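The data were single-cell RNA counts from mouse, made with a modified STRT protocol in which picked cells were reverse-transcribed from an oligo-dT primer that carried a cell barcode and a molecular identifier. The labels describe 40 yolk sac libraries of endothelial cells at 5 stages. Of these, 9 libraries came from E10.0, 10 from E9.5, 9 from E9.0, 10 from E8.5 and 2 from E8.0. A further 3 samples were sorted cells: Gja5+Cd44+ and Gja5-Cd44+ cells of the yolk sac (YS), and Gja5+Cd44+ cells labelled CR, an abbreviation that the labels do not spell out. The labels give no stage for the sorted samples. Each library was taken as a replicate, numbered within its stage in the order of its batch title. The labels do not say which libraries shared embryos or a sequencing run, so the p-values measure the spread between libraries, part of which may be technical.

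The deposited values were whole-number counts per gene symbol and cell. Per the labels, the reads were aligned to mm10. The aligner, the annotation, the collapsing of molecular identifiers and the authors' cell filters are not given in the sources used here, so the values are called counts. The stage files held 23154 gene symbols and no mitochondrially encoded gene. The sorted files held 24414 gene symbols and 92 spike-in rows, which were removed before totals were taken. No cell column was identical to another (0 identical columns). Coordinates were read from the GENCODE M21 annotation of GRCm38, in which 124 of the 129 symbols looked up had 1 position.

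Cells with at least 1000 detected genes and 5000 counts were to be kept, and all 478 stage cells and all 130 sorted cells passed. Stage libraries held 5 to 59 cells, with 82 cells at E10.0, 110 at E9.5, 97 at E9.0, 132 at E8.5 and 57 at E8.0. Total counts per library ran from 2172087 to 15386112 at E10.0, from 3781023 to 13535101 at E9.5, from 3950749 to 31527749 at E9.0, from 3625221 to 42245455 at E8.5 and from 7714983 to 14524234 at E8.0. A stage cell had a median of 589908.5 counts. The median by stage was 417392 at E10.0, 639702 at E9.5, 756537 at E9.0, 730568 at E8.5 and 326040 at E8.0. The sorted samples held 11492877 counts in 50 Gja5+Cd44+ YS cells, 8344180 in 36 Gja5-Cd44+ YS cells and 9185580 in 44 Gja5+Cd44+ CR cells. Intervals and limits from counts cover counting error only, at a confidence level of 95%. Shares of cells in a single sample have exact Clopper-Pearson intervals. A count of 0 was taken to allow up to 3 counts over the group.

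Stage cells were clustered in scanpy 1.11.5 with leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, resolution 1, seed 0). A cluster took the name of a marker list when at least 3 of its members were among the 50 leading genes of the cluster and no other list had as many. This named 3 of the 8 clusters, as arterial-like, megakaryocyte-like and erythroid-like. The rule for the cells called endothelial here was set after the files were seen: the arterial-like cluster and 4 unnamed clusters whose leading genes were not those of blood cells were kept (clusters 1, 2, 3, 7 and 8), and cluster 5 was left out with the megakaryocyte-like and erythroid-like cells. Cluster 5, led by Spi1, Rac2, Mpo and Myb, had 6 hemogenic (Runx1 and Adgrg1 among them), 6 hematopoietic and 4 macrophage genes among its 50 leading genes, and so took no name. It had 19 pan-endothelial genes detected, as did the erythroid-like cluster, and the kept cluster 8 and the megakaryocyte-like cluster had 18. Detection thus did not tell endothelial from blood cells. At a median of at least 10 CPM cluster 5 had 16 of these genes, against 17 in cluster 8, 9 in the megakaryocyte-like and 8 in the erythroid-like cluster. Hemogenic endothelial cells were not separated from blood cells in cluster 5. No doublet caller was run.

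For the comparisons between stages, counts were summed over the cells of each library and tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with TMM normalization, filterByExpr by stage and all 40 libraries in 1 fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The same fit was made on cells of the endothelial clusters from libraries with at least 3 such cells. A stage fold is the log2 ratio of the first stage over the second. Means are of CPM (counts scaled to a common library total) per library, with SD. For the gates inside libraries, cells with a Cd44 count were divided by the presence of a Gja5 count, and cells with a Cdh5 count and no Ptprc count were divided by the presence of a Runx1 count. Sums per library and gate were tested in edgeR with the library as a block, in libraries with at least 3 cells on both sides. The gating genes were left out of the counts of called genes. A list of marker genes was tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, with p adjusted over the lists of a contrast. There were 23 lists: pan-endothelial, arterial, venous, sinusoidal and lymphatic, hemogenic, hematopoietic, erythroid, macrophage, megakaryocyte, lymphoid, mesenchyme, visceral endoderm, S phase, G2/M phase, glycolysis, Notch target, early mesoderm, flow response, fetal RNA-binding, posterior Hox, inflammatory signalling, immediate early and heat shock, and mitochondrially encoded genes. The last list had 0 measured members and gave no result. The lists, the tests, the comparisons and the first set of alternatives were fixed before the data were examined.

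Shares of cells with a Gja5, Cd44 or Runx1 count were taken after each cell was thinned at random to 50000 counts (seed 11). Every stage cell had at least that many. Means over libraries with at least 5 cells were compared between E10.0 and E8.5 with a two-sided exact permutation test in scipy 1.17.1 over 92378 relabellings, adjusted over 6 measures. The sorted samples have no replicate and were given no test. Their log2 ratios used an offset of 5 CPM, and list medians were set against 10000 random lists matched on mean expression (seed 7).

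The genes named are those of a fixed rule. Gja5, Cd44, Runx1, Cdh5, Pecam1 and Ptprc are always named. For E10.0 against E8.5 and for both gates, the rule adds the 8 called genes with the largest fold in each direction at a mean of at least 50 CPM, then up to 12 list members with the smallest adjusted p, at most 3 per list. For the other stage comparisons it adds 4 genes in each direction. For the sorted samples it adds the 8 largest ratios in each direction at 50 CPM or more and with detection in at least 50% of the cells of the higher sample, then up to 8 list members. Genes outside this rule are named as such where they appear. Some genes that the rule names are not reported here.

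The alternatives tried were DESeq2 1.42.0 as the test and as the normalization, no filter on low counts or a mean of at least 20 CPM, limma on per-cell means, depth as a covariate, libraries with at least 10 cells, leaving out each library of a stage comparison, endothelial clusters only, other minimum counts and cell numbers for the gates, thinned cells before gating, no library block, E9.0 to E10.0 only, pooled cells, and other offsets. After seeing the data, fits were added with libraries of consecutive batch numbers summed, without batches 5 to 16, without the E8.0 cells marked 41posi, without Rn45s, with at least 10 counts for a positive cell, and with each library of a gate left out in turn. The procedures were tested on simulated data made from the real counts, with changes of known size added to genes with a mean of at least 20 CPM. Counts were drawn independently and without grouping of libraries by run. The recovery rates below may therefore be too high for the real data, and they do not cover genes at lower levels. The false calls may be too few. At a log2 fold of 2, the fits recovered 80.3% of the changed genes for E10.0 against E8.5, 78.8% in endothelial clusters, 74.2% in the Gja5 gate, 51.5% in the Gja5 gate with at least 10 counts in endothelial clusters and 86.4% in the Runx1 gate. At a log2 fold of 1 they recovered 39.7%, 16.2%, 33.8%, 10.3% and 45.6%, in the same order. False calls were 21 of 165, 10 of 133, 2 of 136, 4 of 92 and 4 of 158.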

Results

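Endothelial cells of the yolk sac give rise to blood cells, and some of them take on arterial features as the vessels mature. Gja5, a gap junction protein of arterial endothelium, and Cd44, an adhesion receptor, mark such cells, and Runx1, a transcription factor, is needed for blood cells to emerge from endothelium. The comparisons address how these genes and the programmes around them differed between stages of the yolk sac, between cells with and without their transcripts, and between sorted cells. In GRCm38 coordinates, Gja5 lies on chromosome 3 (96904693 to 97077416), Cd44 on chromosome 2 (102811141 to 102901665), Runx1 on chromosome 16 (92601466 to 92826149), Cdh5 on chromosome 8 (104101625 to 104144511), Pecam1 on chromosome 11 (106654217 to 106750628) and Ptprc on chromosome 1 (138062861 to 138175708).

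The stage libraries held blood cells beside endothelial cells, in proportions that differed between stages. The arterial-like cluster, led by Gja5, Sparcl1, Aqp1 and Fabp5, made up 79.3% of the cells at E10.0, 34.5% at E9.5, 12.4% at E9.0 and 0% at E8.5 and E8.0. Cells of the megakaryocyte-like cluster, led by the platelet genes Pf4, Gp1bb, Gp9 and Treml1, made up 38.2% at E9.5, 18.6% at E9.0 and 4.55% at E8.5. Erythroid-like cells, led by Hba-x and Klf1, made up 17.4% at E8.5 and 22.8% at E8.0. The clusters kept as endothelial held 79 of 82 cells at E10.0, 54 of 110 at E9.5, 61 of 97 at E9.0, 80 of 132 at E8.5 and 43 of 57 at E8.0. Stage and cluster went together inside this class as well: cluster 7 took 67 of its 70 cells from E8.5, and cluster 8 took 42 of its 45 from E8.0. Single libraries gave most of these cells, with 70% of cluster 7 from E8.5 replicate 10 and 62.2% of cluster 8 from E8.0 replicate 1. The other E8.0 library gave 14 cells of cluster 8. The mix also followed the batch titles, because the 86 cells of batches 5 to 16 (E9.0 and E9.5) were 68.6% megakaryocyte-like and 10.5% endothelial. At E8.5, replicate 10 (batch 37) was 93.2% endothelial, against 16.7% to 50% in the other libraries of that stage.

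**Figure D1:**
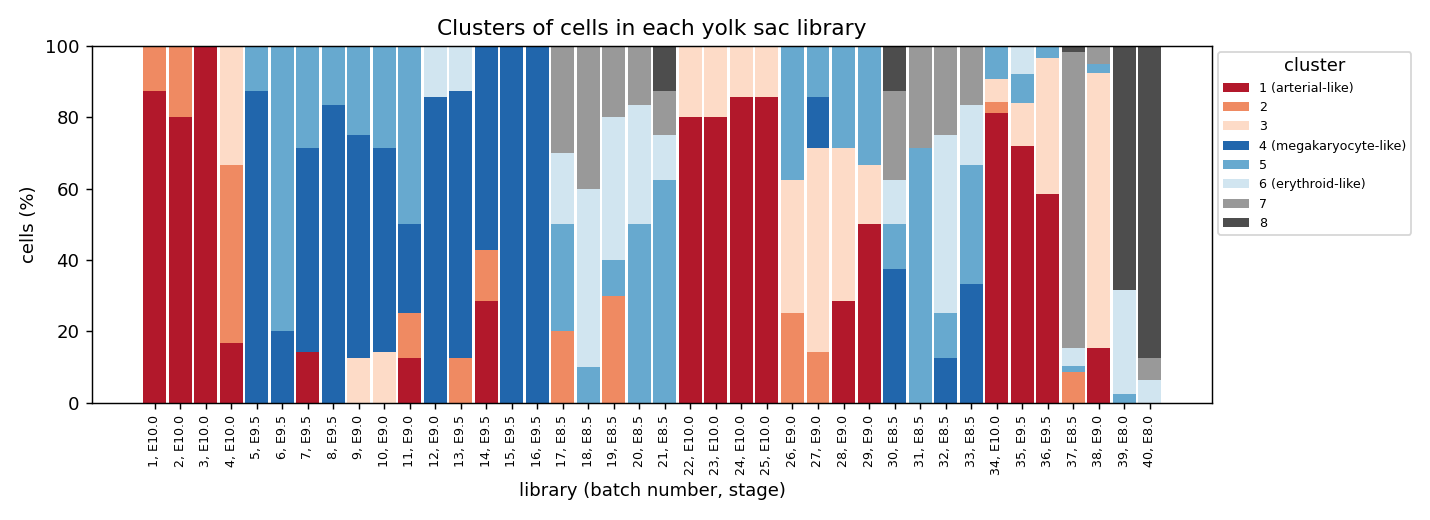
Share of cells (%) in each of the 8 clusters for each of the 40 yolk sac libraries, in the order of the batch number, with the stage below. Batches 5 to 16 are mostly megakaryocyte-like and cluster 5 cells, and the E10.0 libraries are mostly arterial-like.

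Between E8.5 and E10.0 the libraries lost transcripts of blood cells and gained those of mature, arterial endothelium. Gja5, the gap junction gene used for sorting, rose from 1.5 ± 3.08 to 174 ± 230.2 CPM (SD, n = 10 and 9), a log2 fold of 6.67 (SE 1.30, adjusted p = 0.000164). Hpgd, an enzyme that degrades prostaglandins, rose from 2.47 ± 1.61 to 171 ± 116 CPM (adjusted p = 4.03e-09), and Sdpr, a component of caveolae, from 9.80 ± 14.7 to 523 ± 313 CPM (adjusted p = 1.35e-07). Gata1, the transcription factor of red cells and megakaryocytes, was counted at 92.9 ± 46.2 CPM at E8.5 and at 0 in every E10.0 library, at least 1267-fold lower (adjusted p = 7.6e-07). Runx1 fell from 135 ± 65.2 to 6.58 ± 16.3 CPM (log2 fold -4.23, SE 0.901, adjusted p = 0.000462), and Cd44 rose from 25.4 ± 9.77 to 117 ± 70.7 CPM (2.21, SE 0.341, adjusted p = 4.85e-06). In the libraries with the most cells Runx1 lay the other way, at 18.3 CPM in E8.5 replicate 10 and 49.4 CPM in E10.0 replicate 9.

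The endothelial junction genes moved the same way as Gja5. Cdh5, which encodes VE-cadherin, rose by 2.0 on the log2 scale (adjusted p = 0.0102) and Pecam1 by 1.89 (adjusted p = 0.000368). The receptors Kdr and Tie1 rose from 109.8 and 112 CPM to 493 and 334 CPM. Sparcl1, a matrix protein, rose to 279 ± 86.9 CPM from 6.07 ± 7.01, the lipid transporter Cd36 to 145 ± 70.3 from 3.09 ± 4.64, and Fcgrt, which recycles immunoglobulin, to 443 ± 203 from 13.6 ± 15.4. Immune-response genes also rose, with B2m going from 142 ± 67.7 to 1080.0 ± 383 CPM and Ifitm3 rising by 3.73 on the log2 scale. The heat shock genes Hspa1a and Hspa1b rose by 5.64 and 7.31, and Hspa1a varied widely among the E10.0 libraries (305 ± 445 CPM). They are near-identical copies, and how the authors' counting shared reads between them is not given in the sources used here, so their separate levels are uncertain. 8430408G22Rik rose by 5.74 (adjusted p = 0.000363).

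Genes of platelets and red cells, such as Gp1bb and Gata1, were among those that fell. Cited4, a transcriptional coactivator, fell from 419 ± 266 to 0.309 ± 0.461 CPM (log2 fold -10.49, SE 1.28, adjusted p = 7.11e-08). Thbs1, which encodes thrombospondin (log2 fold -9.48), the thrombin receptor gene F2rl2 (-9.03) and the platelet glycoprotein gene Gp1bb (-8.43) fell as well. Gp5, Gnaz and Slc14a1 were at 0 in the E10.0 libraries and were at least 223-fold, 188-fold and 80.8-fold lower. Tal1, a regulator of early blood and endothelium, fell by 2.61. The glycolytic genes Pgk1 (-1.40), Aldoa (-1.07) and Ldha (-1.10) fell, as did the replication gene Mcm2 (-1.30) and the peroxidase gene Prdx2 (-1.27). Ptprc, the pan-leukocyte gene, was called at least 8.33-fold lower (adjusted p = 0.0333), but its E8.5 level of 0.611 ± 1.93 CPM came from 1 library.

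In all, 4317 of 13929 genes were called, 2113 higher and 2204 lower at E10.0, and 3286 of them changed more than 2-fold. DESeq2 called 4348. The share of calls that were higher was 48.9% in edgeR, 53.2% in edgeR with DESeq2's normalization and 54.0% in DESeq2, so the larger direction depended on the normalization. Fewer were called with depth as a covariate (1968) and with consecutive batches summed (40, chosen after seeing the data). Libraries of at least 10 cells left only replicate 9 at E10.0, so no conclusion is drawn from their count of calls. Leaving out each library gave 3966 to 4518 calls.

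Marker lists gave the same picture of endothelium gained and blood lost. Of the 20 arterial genes 19 rose (19 adjusted over the list alone; camera adjusted p = 6.2e-10), and of the 20 pan-endothelial genes 15 rose (18 adjusted over the list alone; adjusted p = 6.25e-10). The venous list (5 of 8 rose, 6 adjusted over the list alone), the flow response list (6 of 9 rose, 6 adjusted over the list alone), the inflammatory signalling list (11 of 18 rose, 11 adjusted over the list alone) and the immediate early and heat shock list (9 of 12 rose, 9 adjusted over the list alone) were also higher at E10.0, with adjusted p of 0.000961, 0.000196, 2.1e-05 and 4.44e-06. Of the 19 hematopoietic genes 13 fell and 2 rose (13 and 2 adjusted over the list alone; adjusted p = 2.1e-05), and of the 12 erythroid genes 8 fell (11 adjusted over the list alone; adjusted p = 0.000196). S phase genes (11 of 14 fell, 13 adjusted over the list alone; adjusted p = 2.27e-05) and glycolysis genes (8 of 15 fell, 9 adjusted over the list alone; adjusted p = 0.000933) were lower. None of these lists passed with an estimated correlation: adjusted p = 0.2 with an estimated correlation for the erythroid list and adjusted p = 0.162 for the others.

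The lymphoid list was higher at E10.0, with 3 of 9 genes called (3 adjusted over the list alone; adjusted p = 0.0437, and adjusted p = 0.235 with an estimated correlation). The called genes, named after their values were seen, were Ebf1, Lck and Il2rg, regulators and receptors of lymphocytes, which rose by 3.85, 3.35 and 1.71 on the log2 scale. In endothelial clusters 0 of the 8 measured lymphoid genes were called by edgeR. The other lists did not pass. Among hemogenic genes 5 of 16 fell and 1 rose (adjusted p = 0.11), and among megakaryocyte genes 6 of 8 fell and 1 rose (adjusted p = 0.0962). Adjusted p was 0.174 for the sinusoidal and lymphatic list, 0.223 for macrophage, 0.11 for Notch target, 0.0676 for early mesoderm, 0.644 for fetal RNA-binding and 0.477 for visceral endoderm genes. For mesenchyme genes the median log2 fold was -0.27 and the mean 0.38, with the test pointing up (adjusted p = 0.477). For posterior Hox genes the median was 0.39 and the mean -0.51, with the test pointing up (adjusted p = 0.646). For G2/M genes the median was 0.15 and the mean -0.04 (adjusted p = 0.848).

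Inside the endothelial clusters arterial and vascular genes rose as well, and some blood genes fell while others were not called or not tested. Gja5 rose from 2.68 ± 4.91 to 182 ± 232 CPM (n = 5 and 9; log2 fold 5.70, SE 1.15, adjusted p = 0.0012), Sdpr from 5.90 ± 9.25 to 543 ± 308 CPM (6.61, SE 0.812, adjusted p = 3.17e-06), and Fabp5, a fatty acid carrier, from 117 ± 42.7 to 3173 ± 1913 CPM (4.76, SE 0.507, adjusted p = 3.06e-07). Klf2, a transcription factor induced by blood flow, rose from 43.6 ± 14.4 to 298 ± 123 CPM, and Stab2, a scavenger receptor of sinusoids, from 193 ± 102 to 1421 ± 712 CPM. The arterial receptor Nrp1 rose by 1.83 on the log2 scale, the thrombin-binding gene Thbd by 2.63 and the growth factor gene Igf2 by 1.54. Lin28a, an RNA-binding protein of early embryonic cells, fell from 95.0 ± 35.3 to 3.32 ± 3.28 CPM (log2 fold -4.78, adjusted p = 8.44e-06), and Gsta4, a glutathione transferase, fell by 8.59. Cd44 rose by 3.02 (adjusted p = 0.000981), Cdh5 by 0.85 (adjusted p = 0.00622) and Pecam1 by 0.89 (adjusted p = 0.00254). Runx1 was lower at 1.32 ± 3.17 against 13.3 ± 21.2 CPM and was not called (log2 fold -3.30, adjusted p = 0.104), and neither were Cited4 (-3.22, adjusted p = 0.18), Thbs1 (-3.56, adjusted p = 0.209) and F2rl2 (-4.15, adjusted p = 0.0986). Gata1 and Gnaz, at 1.77 ± 1.66 and 3.73 ± 4.10 CPM at E8.5 and 0 at E10.0, were called lower (adjusted p = 0.0213 and 0.0198), as were Tal1 (-1.73, adjusted p = 0.0396) and Prdx2 (-0.62, adjusted p = 0.0407). Gp5, Slc14a1 and Gp1bb were too low to be tested there.

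Further genes named in this class were Hpgd (log2 fold 5.41), Aqp1 (4.88), Igfbp7 (4.86), 8430408G22Rik (6.21), Hspa1a (6.18), Hspa1b (9.09), Fos (3.74), Dusp1 (2.18), B2m (2.45) and Ifitm3 (2.87), which all rose. Pgk1 (-1.51), Prkar2b (-3.66), Bex4 (-2.78), Bex2 (-2.85), Tmem69 (-3.26), Gm15645 (-2.57), Tapbpl (-2.41) and A230046K03Rik (-2.27) fell. At E10.0 these cells were mostly cluster 1 and at E8.5 mostly cluster 7, and Gja5, 8430408G22Rik, Hspa1a, Sparcl1, Aqp1, Fabp5 and Igfbp7 were among the genes that lead cluster 1, as Lin28a was for cluster 7 and Gsta4 for cluster 8.

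The fit of 12158 genes called 932, 444 higher and 488 lower at E10.0, with 716 over 2-fold, and DESeq2 called 1325. Of the 929 called genes that the fit over all cells tested, 867 were called there in the same direction and 0 in the opposite direction. Both fits share libraries and cells, 79 of the 82 E10.0 cells among them, so this agreement is not independent. In this class several lists passed with both correlations. The arterial list (11 of 20 rose, 18 adjusted over the list alone; adjusted p = 1.33e-11), the pan-endothelial list (11 of 20, 15 adjusted over the list alone; 1.89e-09), the venous list (3 of 7, 5 adjusted over the list alone; 0.00389), the flow response list (2 of 9, 5 adjusted over the list alone; 0.000131) and the immediate early and heat shock list (8 of 12, 11 adjusted over the list alone; 9.3e-10) had adjusted p = 0.0209 with an estimated correlation. So did the inflammatory list (6 of 18 rose and 1 fell, 7 and 1 adjusted over the list alone; 0.000536). The lower hematopoietic (adjusted p = 0.0131), S phase (0.000425), glycolysis (0.0063), posterior Hox (0.0146) and early mesoderm (0.022) lists passed only with the preset correlation, with adjusted p = 0.153, 0.155, 0.287, 0.438 and 0.0517 with an estimated correlation. Hemogenic genes did not pass (adjusted p = 0.704).

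The share of cells with a transcript of the gating genes differed between the same stages after every cell was thinned to 1 depth. Single libraries were relabelled, although they fell into 3 runs of consecutive batch numbers at each of these stages, and the shares were not tested by run. Cells with a Gja5 count made up 33.1% ± 16.5 of an E10.0 library and 2.45% ± 5.25 of an E8.5 library (n = 9 and 10, exact permutation p = 1.08e-05, the smallest possible, adjusted p = 3.25e-05). Cells with both Gja5 and Cd44, the combination used for sorting, made up 31.5% ± 14.5 and 1.77% ± 4.53 (exact permutation, adjusted p = 3.25e-05). Runx1 went the other way, with 4.02% ± 8.20 at E10.0 and 69.2% ± 22 at E8.5 (exact permutation, adjusted p = 8.66e-05), a difference of -65.1 percentage points. The libraries with the most cells ran against this, with 21.9% in E10.0 replicate 9 and 13.6% in E8.5 replicate 10. In endothelial clusters the Runx1 shares were 3.12% ± 6.19 and 22.4% ± 16.5 (n = 9 and 3, exact permutation, adjusted p = 0.0364), a difference of -19.3 points. With at least 10 counts there, chosen after seeing the data, it was -7.73 and not called (exact permutation, adjusted p = 0.173), and for pooled cells it was -37.2. Cd44 was found in 66.9% ± 24.8 and 42.5% ± 14.2 of the cells (exact permutation, adjusted p = 0.028). Cells with Cd44 and no Gja5 made up 35.4% ± 17.6 and 40.7% ± 13.8 (adjusted p = 0.569 by the exact permutation test), and cells with both Runx1 and Gja5 0.347% ± 1.04 and 0.169% ± 0.536 (adjusted p = 0.737 by the exact permutation test). At E9.5, E9.0 and E8.0, Gja5 was found in 16.1%, 12.8% and 1.22% of the cells and Runx1 in 78.7%, 56.5% and 54.3%.

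Without thinning, Cd44 was not called (77.0% and 66.3%, adjusted p = 0.342 by the exact permutation test), nor was it in endothelial clusters (adjusted p = 0.252, exact permutation) or, chosen after seeing the data, with at least 10 counts (adjusted p = 0.104, exact permutation). Also without thinning, cells with both Runx1 and Gja5 were fewer at E10.0 (4.31% and 23.7%, exact permutation, adjusted p = 0.0406). As a background, erythroid-like cells had a Gja5 count in 2 of 40 cells after thinning and in 17 of 40 without it. Arterial-like cells had one in 53 of 115 cells after thinning. Median depths before thinning were 805186 counts in erythroid-like and 417843 in arterial-like cells. The E8.5 share after thinning was 2.45% as a mean over libraries and 5.30% over pooled cells. Erythroid-like cells had 5% (0.611 to 16.9) and cluster 5 cells 1.82%, so the E8.5 share was not told apart from this background.

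**Figure D2:**
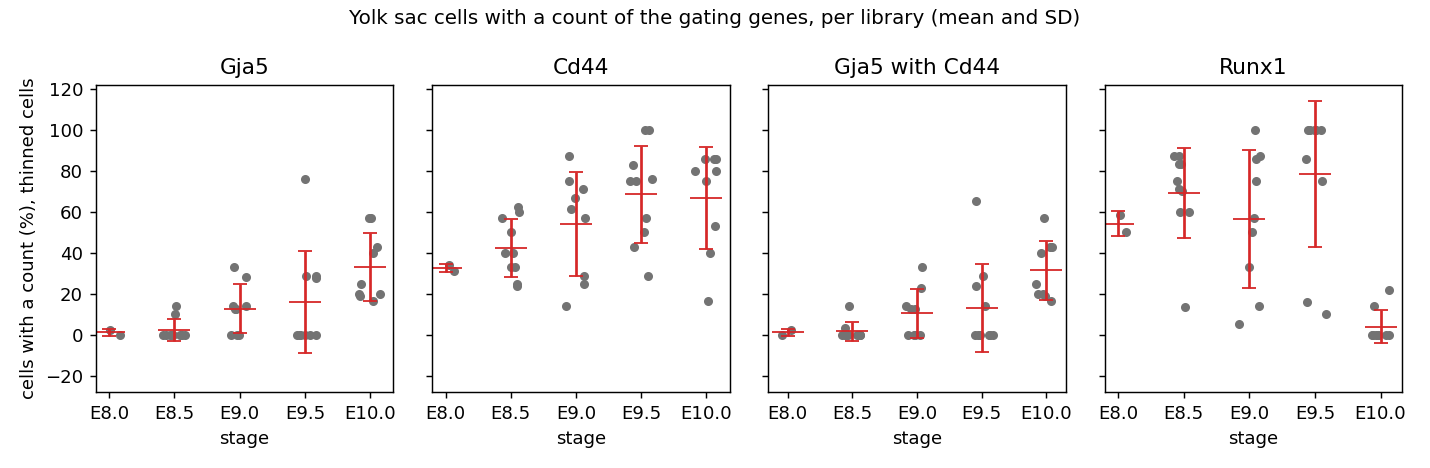
Share of cells (%) with a count of Gja5, Cd44, both, or Runx1 by stage after thinning to 50000 counts; each point is a library and the red bars are the mean and SD, which can pass 0% or 100%. Gja5 was found in 33.1% of the cells at E10.0 and 2.45% at E8.5, and Runx1 in 4.02% and 69.2%.

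From E8.5 to E9.0 the genes that changed included the prostaglandin enzyme gene Hpgd and the caveolar gene Sdpr. Hpgd rose from 2.47 ± 1.61 to 37.1 ± 20.6 CPM (n = 10 and 9; log2 fold 3.93, adjusted p = 0.00052) and Sdpr from 9.80 ± 14.7 to 117 ± 108 CPM (3.58, adjusted p = 0.00367). Both were also called in endothelial clusters, at 4.28 and 4.04. Alox12, a lipoxygenase of platelets, rose by 3.62 over all cells (adjusted p = 0.00312) and was not called in endothelial clusters (1.23, adjusted p = 0.853). Smim14 rose by 2.49, while Pbld1 (-1.89), Cflar (-1.18), March5 (-1.0) and Fam162a (-0.72) fell. Gja5 was at 30.2 ± 45.2 against 1.5 ± 3.08 CPM and was not called (log2 fold 4.15, SE 1.17, adjusted p = 0.0921), nor were Cd44 (1.04, adjusted p = 0.135), Runx1 (0.38), Cdh5 (-0.10) or Pecam1 (0.14).

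The E9.0 fit called 73 genes, 59 higher and 14 lower at E9.0, with 57 over 2-fold, and DESeq2 called 126. In endothelial clusters 9 were called (8 higher, 1 lower; DESeq2 63), and, chosen after seeing the data, 1 with consecutive batches summed and 353 without batches 5 to 16. Libraries of at least 10 cells left only replicate 9 at E9.0, so no conclusion is drawn from their count of calls. Without E8.5 replicate 1, 2, 3, 4, 5 or 8 the count was 41, 41, 40, 42, 48 or 39, and without E9.0 replicate 1 it was 47. Erythroid (adjusted p = 6.24e-08) and glycolysis genes (0.00141) were lower, and immediate early (8.67e-07), megakaryocyte (0.000107) and macrophage genes (0.00598) higher, with adjusted p = 0.122, 0.218, 0.122, 0.238 and 0.122 with an estimated correlation. In endothelial clusters pan-endothelial genes were higher (adjusted p = 0.00125) and hematopoietic genes lower (0.00365), both with adjusted p = 0.214 with an estimated correlation.

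Between E8.0 and E8.5 the endothelial receptor genes Clec14a and Tie1 rose inside the endothelial clusters, by 4.71 and 2.87 on the log2 scale; they were named after their values were seen and were the 2 genes edgeR called there (368 at an unadjusted p under 0.05; DESeq2 33). Over all cells, Runx1 was at 135 ± 65.2 against 56.6 ± 8.41 CPM (n = 10 and 2), Cd44 at 25.4 ± 9.77 against 15.1 ± 3.18, Cdh5 at 140.0 ± 49.4 against 197.5 ± 11.7 and Pecam1 at 111 against 159.9 CPM, and none was called. Gja5 was at 1.5 against 0.107 CPM. The edgeR test over all cells called 0 genes (430 at an unadjusted p under 0.05, where chance gives 696), and DESeq2 called 40. Without E8.5 replicate 3, 7 or 8 edgeR called 2, 1 or 1. Hemogenic (adjusted p = 0.00353), hematopoietic (0.00895) and erythroid genes (0.0102) were higher at E8.5, with adjusted p = 0.43, 0.757 and 0.757 with an estimated correlation. In endothelial clusters the venous list was higher with both correlations (0 called, 2 adjusted over the list alone; adjusted p = 4.07e-06 and, with an estimated correlation, 0.00216). Pan-endothelial (4.4e-06) and posterior Hox genes (1.22e-06) were higher and hematopoietic genes (0.000252) lower there, with adjusted p = 0.0638, 0.17 and 0.0638 with an estimated correlation.

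From E9.0 to E9.5 arterial genes were higher as a group inside the endothelial clusters and lower relative to other genes over all cells, though no single gene passed. Of the endothelial cells, 43 of 61 were in cluster 3 at E9.0 and 38 of 54 in the arterial-like cluster 1 at E9.5. Of these, 30 came from E9.0 replicate 9, and 18 and 17 from E9.5 replicates 9 and 10. Inside the clusters the median log2 fold of arterial genes was 1.96, with 0 called and 8 adjusted over the list alone (adjusted p = 1.68e-11, and adjusted p = 0.0544 with an estimated correlation). Over all cells the test of the arterial list pointed down (adjusted p = 0.000393, and adjusted p = 0.366 with an estimated correlation), while its median was 0.29 and its mean 0.39. There the pan-endothelial (6.67e-08) and venous lists (0.000116) were also lower and the megakaryocyte list higher (0.000663), with adjusted p = 0.348, 0.219 and 0.348 with an estimated correlation. Inside the endothelial clusters the pan-endothelial (adjusted p = 0.0111) and venous lists (0.0345) were higher instead, with adjusted p = 0.261 and 0.237 with an estimated correlation. Gja5 in the endothelial clusters was at 298 ± 185 against 27 ± 35 CPM (n = 3 and 5; log2 fold 3.46, adjusted p = 0.611). The fetal RNA-binding list, which also holds the growth factor gene Igf2 and Dlk1, was lower over all cells with both correlations (adjusted p = 1.3e-06 and, with an estimated correlation, 0.0231). It had 0 genes called and 1 that fell adjusted over the list alone. In endothelial clusters that list did not pass (adjusted p = 0.209, and 0.383 with an estimated correlation). Over all cells Runx1 was at 203 ± 108 against 176 ± 146 CPM, Cd44 at 63.0 ± 33.6 against 52.1 ± 19.9 and Cdh5 at 140.1 ± 229.7 against 131 ± 83.4, and the log2 fold of Pecam1 was -0.23. The edgeR test called 0 genes over all cells (1073 at an unadjusted p under 0.05; DESeq2 4) and 0 in endothelial clusters (884; DESeq2 24). Without E9.5 replicate 9 it called 1.

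From E9.5 to E10.0 platelet genes fell and endothelial genes rose over all cells, while 1 gene was called in endothelial clusters and several named genes turned direction in smaller sets of libraries. Libraries of at least 10 cells left only replicate 9 at E10.0, with Runx1 at 49.4 CPM (9.49 in the nearest E10.0 library). There the log2 folds were 2.11 for Runx1, -1.08 for Cd44, -0.89 for Cdh5 and -0.0535 for Pecam1. Without batches 5 to 16, chosen after seeing the data, the log2 fold was 1.53 for Gp1bb. That fold lies near the floor, since Gp1bb had no count in 8 of the 9 E10.0 libraries. Gp1bb fell from 651 ± 414 to 0.0363 CPM (n = 10 and 9; log2 fold -13.97, adjusted p = 1.06e-05). Gp5, Slc14a1 and Gata1 were at 0 at E10.0 and at least 3331-fold, 2934-fold and 2463-fold lower. Runx1 fell from 203 ± 108 to 6.58 ± 16.3 CPM (-4.81, SE 0.926, adjusted p = 0.000234; endothelial clusters -1.56, adjusted p = 1). Fabp5 rose from 205 ± 245 to 2993 ± 1834 CPM (3.86, SE 0.538, adjusted p = 3.7e-06; endothelial clusters 2.64, adjusted p = 0.117), and Hspa1a by 6.18. Igfbp3, a binding protein of insulin-like growth factors, rose by 3.58 (endothelial clusters 1.30) and 8430408G22Rik by 3.90 (endothelial clusters 2.02). Cd44 rose by 0.90 (adjusted p = 0.0403), Cdh5 by 2.0 (adjusted p = 0.0132) and Pecam1 by 1.97 (adjusted p = 0.000391), against 0.21, -0.07 and 0.31 in endothelial clusters. Gja5 was not called over all cells (174 against 54.7 CPM, log2 fold 1.66, adjusted p = 0.241) and was lower at E10.0 inside the clusters (182 against 298 CPM, -0.71, adjusted p = 1).

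The E9.5 to E10.0 fit called 3732 genes, 1449 higher and 2283 lower, with 2797 over 2-fold (DESeq2 3748). The share of calls that were higher was 38.8% in edgeR and 47.0% in DESeq2. In endothelial clusters, with 3 libraries at E9.5, edgeR called 1 (594 at an unadjusted p under 0.05; DESeq2 15). Over all cells, chosen after seeing the data, 0 were called with consecutive batches summed and 28 without batches 5 to 16. With libraries of at least 10 cells only replicate 9 was left at E10.0, so the count of calls is not given. Pan-endothelial (14 of 20 rose, 19 adjusted over the list alone; adjusted p = 7.41e-16) and arterial genes (9 of 20, 13 adjusted over the list alone; 2.41e-12) were higher, and hematopoietic (13 of 19 fell; 5.22e-07) and megakaryocyte genes (8 of 8 fell; 1.54e-06) lower, all with adjusted p = 0.11 with an estimated correlation. In endothelial clusters immediate early genes were higher (4 adjusted over the list alone; adjusted p = 5.48e-05) and visceral endoderm (0.000531), hematopoietic (0.0361) and megakaryocyte genes (0.0361) lower, with adjusted p = 0.331, 0.342, 0.331 and 0.331 with an estimated correlation.

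Within libraries, cells with Cd44 were compared by the presence of Gja5, and no gene passed, the arterial connexin gene Gja4 included. Gja4 was at 183 ± 251 CPM in cells with Gja5 and 23.5 ± 19.5 CPM in those without (n = 14 libraries; log2 fold 1.95, SE 0.685, higher in 12 of 14). The venous receptor gene Aplnr was at 131 ± 131 against 300.0 ± 300.5 CPM (-1.57, lower in 12 of 14), and the sinusoidal gene Oit3 was lower in 13 of 14 libraries (-1.58). Embryonic globin Hbb-bh1 was at 5631 ± 7894 against 2575 ± 6187 CPM (2.14, higher in 9 of 14), Lmo2 was higher in 12 of 14 (0.94) and the junction gene Esam lower in 11 of 14 (-0.81). The folds of the other named genes were 1.43 for Gfi1b, -1.29 for Clec1b, 1.89 for Hba-x, 0.48 for Prdx2, -1.21 for Emcn, 0.38 for Tpi1, 0.23 for Runx1, -0.63 for Cdh5 and -0.43 for Pecam1. The gate compared 109 with 66 cells, and edgeR called 0 of 9198 genes (332 at an unadjusted p under 0.05; DESeq2 11). Leaving out each library gave 0 calls, and so did the fit in endothelial clusters (181 at an unadjusted p under 0.05). Pan-endothelial (adjusted p = 2.65e-07), venous (0.00176) and sinusoidal genes (0.00278) were lower and hematopoietic (0.000319) and erythroid genes (0.000106) higher, all with adjusted p = 0.471 with an estimated correlation, and arterial genes did not pass (adjusted p = 0.407). In endothelial clusters the arterial list was higher (0 of 15 called, 7 adjusted over the list alone; adjusted p = 5.42e-09, and adjusted p = 0.236 with an estimated correlation). A single count was a weak mark of expression, since 167 of the 236 cells with Gja5 had 1 to 9 counts, and cells outside the endothelial clusters lay on both sides (28 with Gja5 and 21 without at E9.5). Without thinning, 17 of 40 erythroid-like and 33 of 66 megakaryocyte-like cells had a Gja5 count, against 2 and 3 after thinning. Their median depths were 805186 and 851714 counts, against 417843 in arterial-like cells. The part that depth played in the blood and endothelial lists was not tested.

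With at least 10 Gja5 counts for a positive cell and endothelial clusters only, a choice made after seeing the data, the arterial gene Gja4 and 6 other genes rose. Gja4 rose to 943 ± 785 from 96.8 ± 51.2 CPM (log2 fold 3.14, SE 0.383, adjusted p = 0.0046), the chemokine gene Cxcl12 to 66.8 ± 54.2 from 0.661 (6.85, adjusted p = 0.0167), the peptidase gene Ace to 73.2 ± 105 from 2.80 (5.18, adjusted p = 0.0356) and Vwf, the clotting factor of endothelium, to 51.5 ± 36.1 from 0.601 (7.07, adjusted p = 0.0356). Igf2 rose by 1.11, H19 by 1.12 and S100a11 by 1.19. These 7 genes, outside the fixed rule except for Gja4 and Igf2, were all those called, and each was higher in 4 of 4 libraries (32 against 41 cells, 9573 genes). Vegfc (3.75, also named after its value was seen) and Aplnr (-1.09, lower in 4 of 4) had adjusted p = 0.0677. Among arterial genes 1 of 16 was called and 10 adjusted over the list alone (adjusted p = 3.24e-08, and adjusted p = 0.453 with an estimated correlation). Venous (adjusted p = 0.0091) and S phase genes (0.00789) were lower, with adjusted p = 0.636 for both with an estimated correlation. All 7 were also higher in the sorted Gja5+Cd44+ than in the Gja5-Cd44+ yolk sac sample, where 52.0% of the 7446 genes compared had the same direction in both.

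Among cells with Cdh5 and no Ptprc, those with Runx1 carried blood cell transcripts and fewer endothelial ones. This selection did not exclude blood cells, since only 3 of the 478 stage cells had no Cdh5 count and 464 had no Ptprc count. Adgrg1, a receptor of blood-forming endothelium and stem cells, rose to 110.2 ± 100.1 from 4.07 ± 6.08 CPM (n = 10 libraries; log2 fold 4.86, SE 0.730, adjusted p = 0.00489, higher in 10 of 10). Plek, a platelet and leukocyte kinase substrate, rose to 79.8 ± 85.9 from 1.90 ± 3.27 CPM (SE 0.774, adjusted p = 0.00476, higher in 10 of 10), the leukocyte gene Rac2 by 4.55 and the megakaryocyte and red cell factor Nfe2 by 4.59. The cell cycle gene Ccnd2 rose by 1.60 and the Fc receptor gene Fcer1g by 3.31. Endothelial genes fell: Ramp2 from 1480 ± 481 to 940.3 ± 454 CPM (-0.72, adjusted p = 0.01, lower in 10 of 10), and Tie1 (-0.88), Plvap (-0.73), Gpr182 (-1.61), Stab1 (-1.41) and Ushbp1 (-1.66) with it. Igfbp3 (-1.59) and Igf2 (-0.90) fell as well. Rbm38, Psmb10, Rrp9, Prkar2b, Dctpp1 and Tpi1 rose, by 1.91, 1.60, 1.51, 1.38, 1.27 and 0.58, and Stard8 (-1.42), Nrep (-1.33), Slc31a2 (-1.32) and Tspan7 (-1.28) fell. Cdh5 itself was lower in 10 of 10 libraries (-0.91), Pecam1 was not called (-0.78, adjusted p = 0.126), and neither was Cd44 (0.39, adjusted p = 0.779).

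This gate compared 103 with 149 cells and called 138 of 9537 genes, 68 higher and 70 lower (DESeq2 776). In endothelial clusters edgeR called 0 (313 at an unadjusted p under 0.05), with folds of 1.12 for Adgrg1 and 1.70 for Plek. With at least 10 counts in these clusters, chosen after seeing the data, Plek (-0.0692) and Ccnd2 (-0.76) turned direction. Over every stage library, tested or not, 50 cells with Runx1 at E9.5, 31 at E9.0, 51 at E8.5, 14 at E8.0 and 3 at E10.0 lay outside the endothelial clusters, as did 1 cell without Runx1, at E9.0. The count moved with single libraries, to 22 without E10.0 replicate 9, 28 without E8.0 replicate 1, 32 without E8.5 replicate 10, 85 without E9.0 replicate 5, 37 without E9.0 replicate 7, 60 without E9.5 replicate 9 and 311 without E9.5 replicate 10. Pan-endothelial (8 of 19 fell, 15 adjusted over the list alone; adjusted p = 2.01e-10), arterial (1.35e-05), venous (0.00359) and sinusoidal genes (8.31e-05) were lower, with adjusted p = 0.157, 0.176, 0.216 and 0.221 with an estimated correlation. Hematopoietic (3 of 12 rose, 8 adjusted over the list alone; 1.52e-05), hemogenic (1 of 9, 6 adjusted over the list alone; 0.00058), S phase (0.00869) and glycolysis genes (0.00425) were higher, with adjusted p = 0.157, 0.157, 0.237 and 0.245 with an estimated correlation.

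The sorted yolk sac samples parted into arterial cells with Gja5 and cells with more blood-forming transcripts without it. There was 1 sample of each kind, so no test was made and the intervals cover counting alone. Gja5, on which the cells were sorted, was at 1264 CPM (1244 to 1285) in Gja5+Cd44+ cells and at 1 count in Gja5-Cd44+ cells. The arterial gene Gja4 was at 940.4 against 1.08 CPM, and the Notch target Hey1 and the membrane protein gene Tm4sf1 were at 115 and 295 CPM against 0, at least 320-fold and 820-fold higher. Unc5b, a guidance receptor of arteries, was at 229 against 5.63 CPM (log2 ratio 4.46). Runx1 was at 14.6 CPM (12.5 to 17) in Gja5+Cd44+ and 134 CPM (126 to 142) in Gja5-Cd44+ cells (log2 ratio -2.82). It was counted in 13 of 50 cells (26%, 14.6 to 40.3) and in 31 of 36 (86.1%, 70.5 to 95.3), and 1 cell held 51.8% of the Gja5+Cd44+ counts and another 38.9% of the Gja5-Cd44+ counts.

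Other genes higher in Gja5+Cd44+ cells were Tmem100 (log2 ratio 5.49), Slc45a4 (4.93), Atf3 (3.01), Ecscr (2.58), Cdh5 (2.06), Cd44 (2.01), Pecam1 (1.84) and Serpinf1 (at least 505-fold), and Adgrg6, with 1 count in Gja5-Cd44+ cells, had a log2 ratio without offset of 8.82 to 16.60. A row named RGC-GFP, which the labels do not describe, held 6500.5 CPM in Gja5+Cd44+ YS cells and 0 in the Gja5-Cd44+ sample, at least 18080-fold higher. Leukocyte and platelet genes were lower, among them Ptpn7 (-3.80), Ptgs1 (-3.68), Ptpn6 (-3.67), Bin2 (-3.59), Rac2 (-3.49), Plek (-2.99), the myeloid gene Lyz2 (-2.79) and Gata1 (-2.58). Dhodh was also lower (-3.48), Cited1 was at least 254-fold lower, and Mettl13, with 2 counts, lay between -11.45 and -6.53. Ptprc was at 0 in Gja5+Cd44+ cells and at 12.8 CPM in Gja5-Cd44+ cells, of which 1 cell held 83.2%.

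The arterial list had a median log2 ratio of 2.95, with 19 of 19 genes higher (percentile 100 of the random lists), and the pan-endothelial list 1.04 (20 of 20 higher, percentile 100). The flow response (0.90, percentile 99.7) and immediate early lists (0.87, 12 of 12 higher, percentile 99.9) were also high. Hematopoietic (-1.52, 1 of 19 higher, percentile 0), hemogenic (-0.81, 4 of 16, percentile 0.02), macrophage (-1.40, percentile 0.075), S phase (-0.63, percentile 0.22) and visceral endoderm genes (-2.14, percentile 0) were low. The lymphoid median was 0.45, with 7 of 11 genes higher and a percentile of 86.1.

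**Figure D3:**
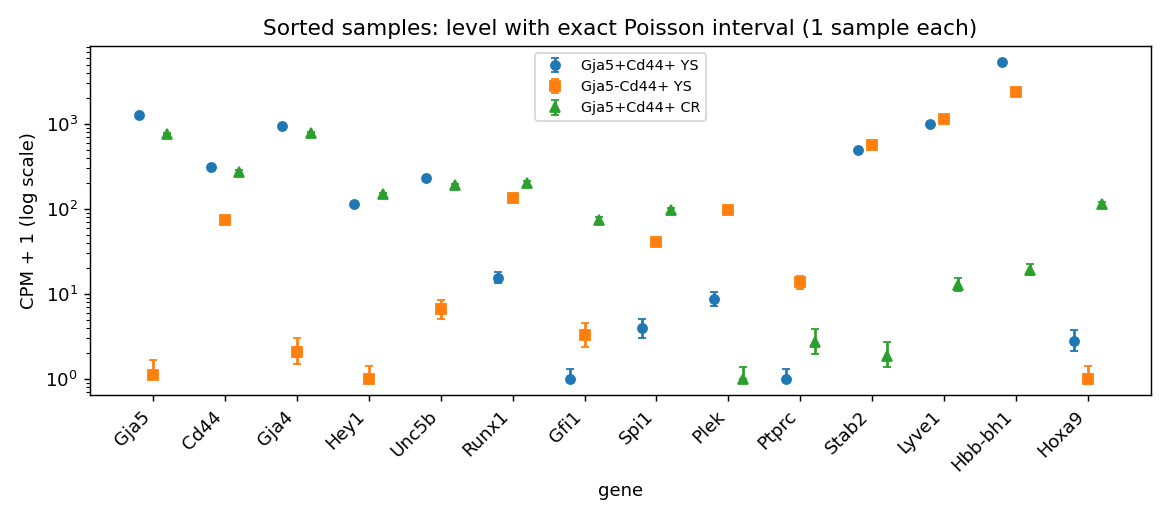
Level of 14 genes in CPM + 1 on a log scale in the 3 sorted samples, with exact Poisson intervals of counting error and 1 sample per kind. Runx1 was at 14.6 CPM in Gja5+Cd44+ YS, 134 CPM in Gja5-Cd44+ YS and 202 CPM in Gja5+Cd44+ CR cells.

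Sorted with the same markers, yolk sac and CR cells differed in blood, sinusoidal and positional genes, and arterial genes were somewhat higher in the yolk sac. Gja5 was at 1264 CPM in the yolk sac and 765 CPM in CR cells (log2 ratio 0.72, 0.68 to 0.77), and the ratios of Cd44, Cdh5 and Pecam1 were 0.18, 0.73 and 0.62. Runx1 was lower in the yolk sac, at 14.6 against 202 CPM (-3.40), with CR cells positive in 41 of 44 (93.2%, 81.3 to 98.6). Gfi1, a repressor that acts with Runx1 in blood formation, was at 0 against 73.4 CPM, at least 281-fold lower, and the myeloid factor Spi1 was at 2.96 against 95.3 CPM. Hoxa9, a gene of posterior position, was at 1.83 against 112 CPM (-4.10). Embryonic globins were far higher in the yolk sac cells, with Hbb-bh1 at 5355 against 18.3 CPM (7.85), as were the sinusoidal receptor genes Stab2 (488 against 0.871 CPM, 6.39) and Lyve1 (1003 against 11.9 CPM, 5.90). Hba-x was also high in the Gja5-Cd44+ yolk sac cells, at 4894 CPM, of which 1 cell held 39.2%.

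The metallothionein genes Mt1 (7.67) and Mt2 (6.97), the globins Hba-x (7.31) and Hbb-y (7.15), the red cell gene Slc4a1 (4.99), and Col1a1 (4.49), Maf (4.41), Aplnr (4.03), Dlk1 (3.59) and Col3a1 (3.58) were higher in the yolk sac. Hspa1a was at least 189-fold higher. Mrc1, with 3 counts in CR cells, lay between 8.26 and 12.09, and Alas2, with 1 count, between 8.71 and 16.50. Fam181b (-3.53) and D16Ertd472e (-3.46) were lower, Pla2g16, with 3 counts in the yolk sac, lay between -9.95 and -6.12, and Ptprc was at least 6.67-fold lower, from 16 counts in 1 CR cell. Among lists, the erythroid (median 4.27, 12 of 12 higher, percentile 100), sinusoidal and lymphatic (3.07, percentile 100), G2/M (0.58, 14 of 14, percentile 99.9), arterial (0.52, 15 of 19, percentile 99.95) and pan-endothelial lists (0.33, 14 of 20, percentile 99.6) were high. Hemogenic (-2.06, 2 of 16 higher, percentile 0), posterior Hox (-0.97, 2 of 14, percentile 0.11), S phase (-0.66, percentile 0.01) and fetal RNA-binding genes (-0.65, percentile 0.2) were low.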

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

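The depth test of the E10.0 to E9.5 calls was chosen only after the result was seen; the other tests in this part were set before their results were seen, except that the spread of the slopes over left-out libraries replaced a resampling of genes after the first value was seen.

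In 19 cases a library lay far from the others of its stage. Out of 59 groups of values examined, about 2.95 such cases come by chance, 1 in 20, if values are normally distributed. Shares of few cells and skewed CPM need not be, so more may come by chance. The libraries with the most cells stood out in total counts, with 15386112 in E10.0 replicate 9 (next 4982006), 42245455 in E8.5 replicate 10 (next 9362504) and 31527749 in E9.0 replicate 9 (next 7966037). The median number of detected genes in E8.5 replicate 10 was 7148 (nearest 7837). In thinned cells Runx1 was found in 13.6% of the cells of E8.5 replicate 10 (nearest 60%). Runx1 with Gja5 was found in 3.12% of the 32 cells of E10.0 replicate 9, 1.69% of the 59 of E8.5 replicate 10 and 2.56% of the 39 of E9.0 replicate 9 (nearest 0 in each stage). Such shares can rest on 1 cell. Gja5 with Cd44 was found in 14.3% of the 7 cells of E8.5 replicate 7 (nearest 3.39%) and 65.5% of E9.5 replicate 10 (nearest 28.6%), and Gja5 in 75.9% of E9.5 replicate 10 (nearest 28.6%). Gja5 was at 733 CPM in E10.0 replicate 7 (nearest 340.2), 10.2 in E8.5 replicate 10 (nearest 1.48), 137 in E9.0 replicate 3 (nearest 61.9) and 344 in E9.5 replicate 10 (nearest 109). Ptprc was at 6.11 CPM in E8.5 replicate 8 (nearest 0), 3.03 in E9.0 replicate 8 (nearest 1.44) and 1.17 in E9.5 replicate 9 (nearest 0). Runx1 was at 49.4 CPM in E10.0 replicate 9 (nearest 9.49).

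The many genes called between E9.5 and E10.0 over all cells may come in large part from the mix of cell types. Over the 3082 called genes measured in both fits, the slope of the fold in endothelial clusters on the fold over all cells was 0.544 (0.508 to 0.571 as each library was left out), above the 0.5 set as the bound; that bound excludes nothing, because the fits share 79 of the 82 E10.0 cells and no slope without a change is known, so the mix stays open. The call count fell to 1 there, as the median absolute log2 fold dropped from 1.45 to 0.446 and only 3 libraries of E9.5 were left. With depth in the fit 2286 genes were called, against 3732 without it, which argues against depth as the whole source. How many genes were in both was not counted, so depth as a part of it stays open. For E10.0 against E8.5 the counts were 1968 with depth and 4317 without it, so depth stays open there too. Library run stays open, since 28 genes were called without batches 5 to 16, and then with 2 libraries at E9.5; a change with stage was not separated from it.

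Immediate early and heat shock genes were higher at E10.0 than at E8.5 in endothelial clusters. The lowest mean of a run of E10.0 libraries (mean log2 of CPM + 1 over the list) was 6.11, above the highest E8.5 library at 4.71, so a single run of libraries is unlikely to be the source. With depth in the fit the median log2 fold was 2.716, against 2.725 without it, which argues against depth. Handling or quality of the cells was not tested and is confounded with stage (library median of detected genes 5873.5 ± 914 at E10.0 and 8030.8 ± 373 at E8.5; Rn45s 2.80% ± 1.41 and 1.45% ± 0.504 of counts), and a change with stage stays open too. It need not be a steady one, since the list was lower at E8.5 than at E8.0 (adjusted p = 0.00128 by camera, and adjusted p = 0.305 with an estimated correlation), where the libraries were at 5.38 and 4.80.

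The genes called between Runx1+ and Runx1- cells may reflect cells outside the endothelial clusters among the positive cells. Over the 135 called genes measured in both fits, the slope of the fold in endothelial clusters on the fold over all gated cells was 0.333 (0.288 to 0.398 as each library was left out), under the bound of 0.5. The median absolute log2 fold dropped from 0.962 to 0.345, with 97.8% of the genes in the same direction. The clusters left out include cluster 5, whose leading genes hold Runx1, Adgrg1 and Rac2 themselves, so the drop does not tell blood cells from hemogenic endothelium, and both stay open, as does a smaller difference inside the clusters kept.

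Other splits of the same libraries, 71 for each stage comparison with the real one included, were counted for genes called. Among splits of single libraries, only the real split gave as many calls in the comparisons that follow, which argues against chance at that level. These were E10.0 against E8.5 (4317 called, at most 875 in another split), E9.0 against E8.5 (73, at most 1), E10.0 against E9.5 (3732, at most 414) and E10.0 against E8.5 in endothelial clusters (932, at most 111). These splits did not keep libraries of consecutive batch numbers together, and with such libraries summed 40, 1, 0 and 662 genes were called in the same order by edgeR, so grouping by run stays open over all cells, and less so in endothelial clusters. For E9.5 against E9.0 edgeR called 0 (1073 at an unadjusted p under 0.05; DESeq2 4), which all 71 splits reach by construction, so the splits decide nothing. Another split there called 162, which points to a structure among these libraries. For the Runx1 gate only the real split gave as many calls (138 called, at most 1 in another of 41 splits), which argues against chance among these libraries. The count was 3 with at least 5 cells per gate, 6 without a library block and 22 to 311 as each library was left out. For the Gja5 gate edgeR called 0 (332 at an unadjusted p under 0.05; DESeq2 11; at most 0 in another split), which all 26 splits reach by construction, so they decide nothing either. For the Gja5 gate with at least 10 counts in endothelial clusters (7 called, at most 0 in another), 8 splits are too few for a share under 0.05.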

How the results depend on the processing

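Summed batches, batches 5 to 16, 41posi cells, Rn45s, the 10-count minimum and the leaving out of gate libraries were tested only after the data were seen.

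For E10.0 against E8.5, 932 genes were called in endothelial clusters, 1968 with depth as a covariate, 282 in libraries of at least 10 cells, 40 with consecutive batches summed and 662 with both endothelial clusters and summing, where Gp1bb reversed to 2.09. For E8.5 against E8.0, DESeq2 called 40, limma 17, a mean of at least 20 CPM 1, endothelial clusters 2, depth 2, at least 10 cells 3, without batches 5 to 16 2, and without 41posi cells 2. For E9.0 against E8.5, DESeq2 called 126, endothelial clusters 9, at least 10 cells 23, summed 1, endothelial and summed 40, and without batches 5 to 16 353. For E9.5 against E9.0, DESeq2 called 4, limma 4, endothelial and summed 4, and without batches 5 to 16 2. Libraries of at least 10 cells left only replicate 9 at E10.0 and at E9.0, and summing left 1 sample at E8.0. The counts above for at least 10 cells in E10.0 and E9.0 against E8.5 thus rest on 1 library at the later stage. They hold no spread between libraries of that stage, so no conclusion is drawn from them. The other counts of calls that rest on such fits are not given.

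For E10.0 against E9.5, a mean of at least 20 CPM gave 2485, limma 6073, depth 2286, endothelial clusters 1, summed 0, endothelial and summed 6, and without batches 5 to 16 28. Its reversed folds were Cdh5 at -0.0736 (endothelial clusters), -0.89 (at least 10 cells) and -0.14 (endothelial and summed), Cd44 at -1.08, Runx1 at 2.11 and Pecam1 at -0.0535 (at least 10 cells), and Gp1bb at 1.53 (without batches 5 to 16). A mean of at least 20 CPM tests fewer genes, and the endothelial, 10-cell and summed fits have fewer libraries or cells. The 10-cell fit has only replicate 9 at E10.0, and Gp1bb had no count in 8 of the 9 E10.0 libraries. Otherwise the cause was not tested.

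In the Gja5 gate DESeq2 called 11, no filter 16, thinning 12, at least 10 counts 9, and at least 10 counts in endothelial clusters 7. In the Runx1 gate DESeq2 called 776, no filter 637, at least 5 cells 3, at least 2 counts 225, thinning 222, no library block 6, E9.0 to E10.0 alone 1, endothelial clusters 0, at least 10 counts 830, and at least 10 counts in endothelial clusters 1, where Ccnd2 (-0.76) and Plek (-0.0692) reversed; the cause was not tested.

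The difference in the share with Cd44 (24.4 percentage points) was 10.7 without thinning, 24.5 in endothelial clusters, 18.7 with at least 10 counts and 21.1 with both, and was called in none of these (exact permutation, adjusted p = 0.342, 0.252, 0.104 and 0.402). That with Runx1 (-65.1) was -19.3 in endothelial clusters, -7.73 with at least 10 counts in endothelial clusters (not called, exact permutation, adjusted p = 0.173) and -37.2 for pooled cells, and that with Runx1 and Gja5 reversed to -19.4 without thinning. With an estimated correlation the lists past the threshold over all cells went from 47 to 1 between stages and from 14 to 0 in the gates. The sorted Gja5 ratio of YS to CR was 0.86 from means over cells.

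Leaving out each library gave 3966 to 4518 calls for E10.0 against E8.5, 0 to 2 for E8.5 against E8.0, 39 to 80 for E9.0 against E8.5, 0 to 1 for E9.5 against E9.0, 3200 to 4438 for E10.0 against E9.5, 0 to 0 in the Gja5 gate and 22 to 311 in the Runx1 gate. Of the values for the 33 genes named for E10.0 against E8.5, 410 of 487 kept their side of the threshold, 76 were weaker and 1 reversed, and 626 of 626 kept it as each library was left out. With libraries left out, 213 of 264 kept it for E9.0 against E8.5, 255 of 266 for E10.0 against E9.5 and 230 of 318 in the Runx1 gate. Under the other alternatives it was 148 of 202 for E10.0 against E9.5, 167 of 205 for E9.0 against E8.5, 174 of 184 in the Gja5 gate and 227 of 372 in the Runx1 gate. The cell filters removed no cell, so the alternatives without them and with stricter ones tested nothing. Their unchanged values are counted among those that kept their side of the threshold. At least 100 CPM gave no value for the sorted direction of gate calls. The largest shift of the median of all genes (log2) was 0.0690 by scaling alone and 0.0727 with the DESeq2 test as well.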

Other observations

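The shares of genes with the same direction in the sorted pair were computed for these sets of genes only after the gate results were seen. The planned share, over genes called in the Gja5 gate, had no value because 0 genes were called (332 at an unadjusted p under 0.05 in edgeR; DESeq2 11). Of the genes with an unadjusted p under 0.05 in that gate, 101 of 284 (35.6%) had the same direction in the sorted Gja5+Cd44+ and Gja5-Cd44+ yolk sac samples, against 43.0% of all 7394 genes compared. With the gate kept to endothelial clusters it was 112 of 161 (69.6%), against 54.0% of 7204.

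Libraries with consecutive batch numbers resembled each other more than the rest of their stage at E9.0 (mean correlation of residuals across genes 0.278 within runs and -0.321 between them) and E9.5 (0.203 and -0.199), and less so at E8.5 (-0.0371 and -0.148) and E10.0 (-0.115 and -0.119). These are correlations across genes, which are not independent replicates.

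The other list medians of the sorted yolk sac pair were -0.64 for venous (percentile 4.12), -0.15 for sinusoidal and lymphatic (33.4), 0.38 for erythroid (96.0), -0.93 for megakaryocyte (2.19), -0.08 for mesenchyme (39.6), -0.11 for G2/M (54.5), -0.34 for glycolysis (13.4), 0.33 for Notch target (86.7), 0.21 for early mesoderm (68.4), 0.14 for fetal RNA-binding (73.9), 0.43 for posterior Hox (95.0) and 0.43 for inflammatory genes (96.4). Against CR cells they were 0.65 for venous (98.1), -0.27 for hematopoietic (22.9), 0.33 for macrophage (89.8), -0.17 for megakaryocyte (44.7), 0.23 for lymphoid (80.1), 0.49 for mesenchyme (99.6), 0.20 for visceral endoderm (84.3), -0.43 for glycolysis (2.21), 0.15 for Notch target (82.6), -0.44 for early mesoderm (17.3), 0.43 for flow response (97.5), 0.12 for inflammatory (81.1) and 1.02 for immediate early genes (100).

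The E8.0 cells carried marks that the labels do not explain, with 39 marked 41neg and 18 marked 41posi.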
